A study of Homo sapiens with 2 samples.

How the data were processed

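Total RNA was extracted with Trizol from SW620 cultures grown in RPMI medium, turned into biotin-labelled cRNA with an Affymetrix 3′ in vitro transcription kit and hybridized to 1 array per culture, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes quantiles between arrays and summarises the probes of a probe set. Its version and settings, and which arrays it was run on together, are not given in the sources used here. RMA usually returns log2 values; the linear scale was read from the values, which reach 23253, and the step that returned them to that scale is not given in the sources used here. Quantile normalization forces arrays to a like distribution, so a change in total RNA per cell cannot be seen, and summarised values carry no detection call. In 1128 probe sets the value was identical on both arrays, at a median log2 level of 4.72.

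The labels placed 1 array in the mock knockdown group and 1 in the SOX2 knockdown group. The source names read knockdown, while the titles end in KO. Of 54675 probe sets, 62 were array controls and were used only for quality. A platform annotation named 1 gene symbol for 41092 of the others, several for 1800 and none for 11721, and the last 2 kinds were left unnamed. Of the probe sets with 1 symbol, 41043 were found by Entrez identifier in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. That table was used only for names and for the order of genes along chromosomes, since no build is given for the probe sets.

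From the deposited intensity, log2 values were taken with no pseudocount and no further normalization. The value of a gene was that of its probe set with the highest mean over both arrays. A gene entered when the higher of its values reached the floor, the median of all values other than controls, 68.5. Of 19776 genes with a probe set of their own, 13609 entered. With 1 array per group no test was run and genes were counted by a fixed limit of 2-fold. Where the dimmer value lay under the floor, the fold or difference of a named gene was taken against the floor and is given as a bound. Ranks, counts and list medians used the values as deposited, and raising values under the floor to the floor was an alternative added after the data were seen. The agreement of probe sets of 1 gene within this pair of arrays served as the measure of spread. It holds no variation between cultures, extractions or arrays, which all probe sets of a gene share.

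A set of 36 gene lists was written down before the data were examined, as were the floor, the limit of 2-fold, the rule for named genes and the alternatives below. The rule took SOX2, the 15 largest positive and 15 largest negative differences among genes whose probe sets reaching the floor all went the same way, leaving out provisional symbols, up to 2 members of each list in each direction with at least 1.5-fold difference, and ECM1. For each list with at least 5 measured genes, the median difference was set against 10000 random lists of equal size, drawn from 20 bins of mean level. A list was said to lie outside the random range when its median was under the 2.5 or over the 97.5 percentile.

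The alternatives were other normalizations between the arrays (median centring, intensity-dependent centring, quantiles), other floors, other choices of probe set per gene, a pseudocount of 32, other limits of size, means in place of medians and random lists not matched on level. The counting step was tested on simulated data for the comparison of SOX2 knockdown with mock knockdown, over 13359 genes with noise of SD 0.15 on each array. Changes were planted only in genes with a mean more than 2 log2 units above the floor, so recovery of dimmer genes was not tested. The step recovered 100% of 100 genes changed 4-fold and 96% of 100 changed 2.46-fold, with 0 unchanged genes called. With an SD of 0.5 for the difference, close to the spread between probe sets, it recovered 99% and 72%, and 643 of 13510 unchanged genes passed the limit of 2-fold. With noise of SD 0.15 on each array, a simulated list shifted by -0.5 fell at percentile 0, and 2 of 33 other lists lay outside the range. The real differences had a scaled median absolute deviation of 0.44, and a list shift was not simulated at that spread. In simulated data the correlation along chromosomes was 0.0008 with nothing planted and 0.0643 with 4 chromosomes shifted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.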

Results

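Gene expression was measured on 2 single-colour Affymetrix 3′ expression arrays in SW620, an established human line derived from a lymph node metastasis of a colorectal cancer. One culture carried a lentiviral short hairpin RNA against SOX2, a transcription factor of pluripotent and neural progenitor cells, and the other a non-targeting hairpin, called mock knockdown. The design texts put the question of which genes SOX2 controls in colorectal cancer cells. They also mention gastrulation, which no sample matches. Each group held 1 array, so there were no replicates, no difference could be tested and the number of arrays limits the precision of every value. Each array gave values for 54613 probe sets apart from controls, with a median intensity of 69.0 on the mock array and 68.1 on the SOX2 knockdown array. The values ran from 5.74 to 23253 and from 5.72 to 21562. A floor was set at the median of all values, 68.5, or 6.10 on the log2 scale. It was reached by 27415 probe sets on the mock array and 27198 on the SOX2 knockdown array, and 13609 genes reached it on at least 1 array. All differences are SOX2 knockdown minus mock knockdown on the log2 scale. Where a gene lay under the floor on 1 array, its difference is given against the floor, as a bound. Such a bound holds for the gene's brightest probe set, and other probe sets of the gene can differ by less. Counts and medians of gene lists use the values as deposited.

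SOX2 itself was lower on the array labelled SOX2 knockdown. Its brightest probe set, 228038_at, stood at an intensity of 2077 on the mock array and 20.9 on the SOX2 knockdown array, a log2 difference of -6.64 as deposited. Because the lower value lay under the floor, only a bound holds, and SOX2 was at least 30.3-fold lower. A further probe set of SOX2, 213721_at, went from 333 to 120, a log2 difference of -1.47, with 36.2% of the mock value left. The remaining probe sets of SOX2, 214178_s_at and 213722_at, stayed under the floor on both arrays, with differences of -0.06 and -0.42. The size of the difference in SOX2 therefore depended on the probe set, and both probe sets that reached the floor were lower.

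**Figure D1:**
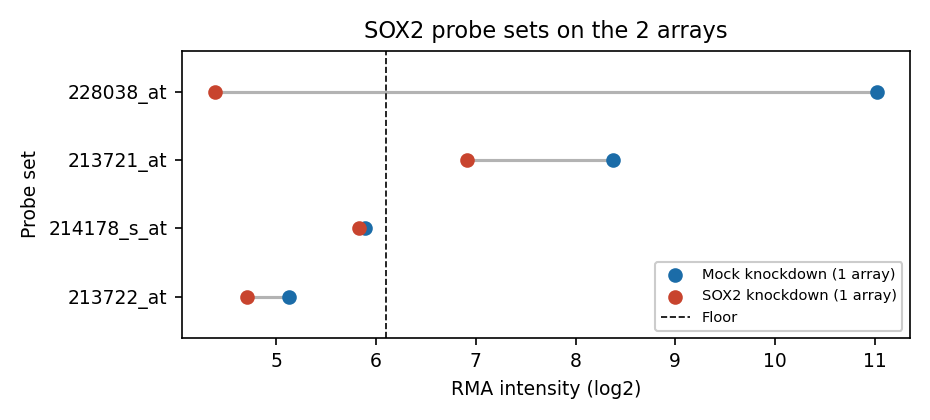
Log2 intensity of the 4 SOX2 probe sets on the mock knockdown and the SOX2 knockdown array, 1 array each, with the floor of 6.10 drawn as a dashed line. The probe set 228038_at stood at 11.02 on the mock array and 4.39 on the SOX2 knockdown array, and 213721_at at 8.38 and 6.91; the remaining probe sets lay under the floor on both arrays.

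The 15 largest positive differences as deposited were named by rule. The membrane trafficking protein MAL2 was at least 124-fold higher on the SOX2 knockdown array, with an intensity of 14.4 on the mock array and 8474 on the other. KRT20, a keratin of differentiated intestinal cells, was at least 157-fold higher, with 23.2 against 10763. The tetraspanin-like TM4SF4 was at least 121-fold higher and LGALS4, a galectin of the gut epithelium, at least 87.7-fold higher. MMP7, a matrix metalloproteinase, went from 152 to 10310 and was 68.0-fold higher, the only one of the 15 above the floor on both arrays. The glutamate transporter SLC1A1 was at least 49.7-fold higher, the circadian repressor BHLHE41 at least 36.9-fold, the annexin ANXA10 at least 32.4-fold, the kinase DAPK1 at least 29.7-fold and the iron exporter SLC40A1 at least 28.8-fold. The retinaldehyde dehydrogenase ALDH1A1 was at least 27.3-fold higher, the drug efflux pump ABCG2 at least 25.8-fold, the methyltransferase NNMT at least 24.3-fold, the cornified envelope gene SPRR1B at least 18.3-fold and TMEM30B at least 14.1-fold. A further probe set of SLC40A1 differed by 0.24 and one of TMEM30B by 0.10. Other probe sets of SLC1A1 and NNMT also differed by less than the bounds given, at 1.46 and 1.07.

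The 15 largest negative differences as deposited were named by the same rule. VIM, the intermediate filament of mesenchymal cells, went from 8652 to 72.2 and was 120-fold lower. It was the only one of the 15 above the floor on both arrays, though 72.2 lay close to the floor of 68.5. The neuropeptide gene GAL was at least 96.5-fold lower, with 6614 on the mock array and 31.4 on the SOX2 knockdown array. SYT1, a synaptic vesicle protein, was at least 55.7-fold lower. ELOVL5, a fatty acid elongase, was at least 74.4-fold lower, but another of its 3 probe sets differed by only -0.42. BEX3 was at least 76.7-fold lower, the T cell receptor constant region TRBC1 at least 71.4-fold, the claudin CLDN11 at least 43.2-fold, the actin-binding CALD1 at least 38.1-fold and TMEM47 at least 36.0-fold. The list also held SOX2, the imprinted gene PEG10, at least 27.1-fold lower, HDGFL3, at least 26.9-fold, the axon guidance receptor ROBO1, at least 26.2-fold, the isomerase ECI2, at least 22.2-fold, and PWWP3B, at least 16.9-fold. Another probe set of CLDN11 differed by -0.63 and one of the 5 of CALD1 by -0.50. Other probe sets of PEG10, TRBC1, HDGFL3 and TMEM47 also differed by less than the bounds given, at -2.69, -2.92, -3.15 and -4.81.

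Of the 13609 genes, 1148 were at least 2-fold higher on the SOX2 knockdown array and 992 at least 2-fold lower, together 15.7%. On the dimmer array, 319 of the higher genes and 300 of the lower genes lay under the floor. With values under the floor taken at the floor, 1068 genes were at least 2-fold higher and 903 lower. Against the floor, 55 higher and 38 lower genes differed by at least 16-fold, and 5 and 5 by at least 64-fold. With a limit of 1.5-fold the counts were 2044 higher and 2012 lower, and with a limit of 3-fold they were 604 and 467. The median difference was -0.0063, with a scaled median absolute deviation of 0.44 on the log2 scale, and 70.2% of genes lay within 1.5-fold. Pearson's r between the arrays was 0.847 across these genes, which are not independent replicates. Where a gene had several probe sets and its brightest differed by at least 2-fold, all of them went the same way in 951 of 1077 genes, or 88.3%, and all differed by at least 2-fold that way in 508, or 47.2%. The spread between probe sets of a gene was an SD of 0.49 on the log2 scale. Differences also followed the order of genes along chromosomes: across 12383 genes reaching the floor on both arrays, differences of genes 20 to 60 apart correlated at 0.105 when limited to 1 either way, and at 0.0755 when not limited. In 1000 shuffles of gene order the correlations reached at most 0.0041 and 0.0045. All group differences below were measured on this same pair of arrays.

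**Figure D2:**
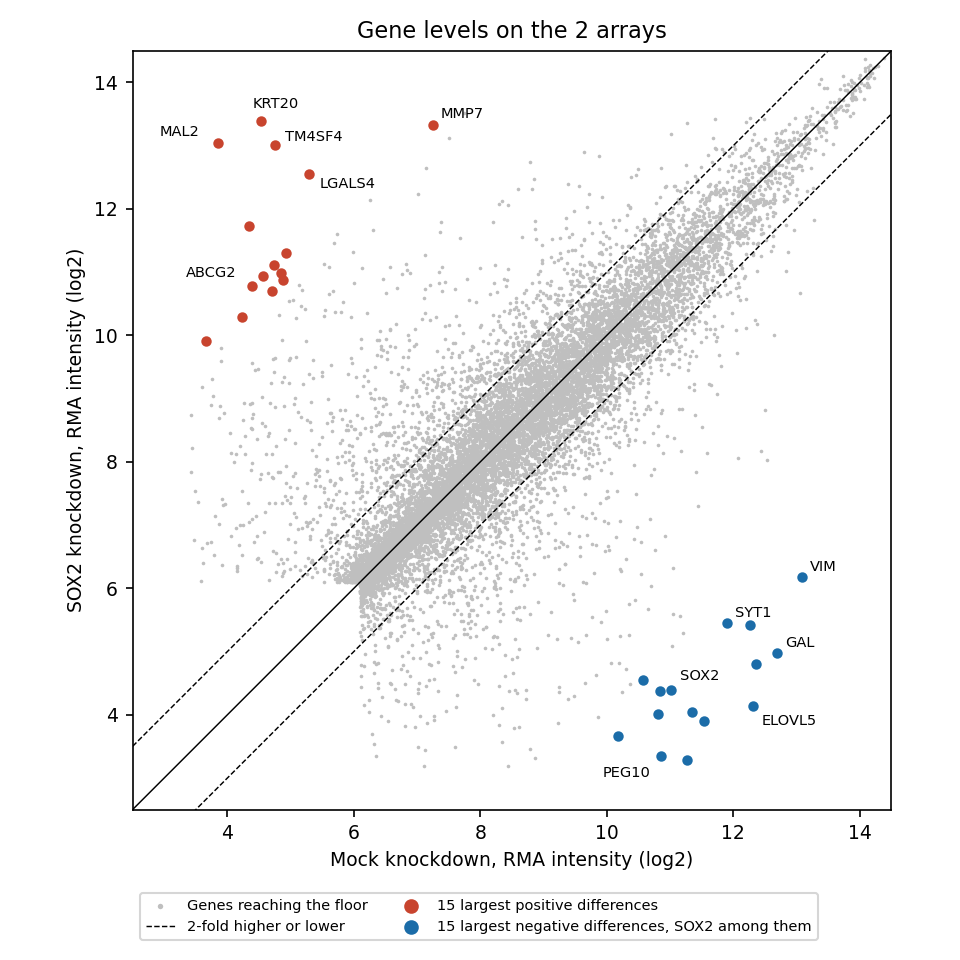
Log2 intensity of the 13609 genes reaching the floor on the mock array (horizontal axis) and the SOX2 knockdown array (vertical axis), 1 point per gene, with lines at no difference and at 2-fold. The 15 largest positive differences, among them MAL2 (3.85 and 13.05) and KRT20 (4.53 and 13.39), lie at upper left, and the 15 largest negative ones, among them VIM (13.08 and 6.17) and SOX2 (11.02 and 4.39), at lower right.

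Interferon-stimulated genes were higher on the SOX2 knockdown array. All 23 measured members of the type I interferon list lay above 0, 18 of them at least 2-fold, and the median difference was 1.47. The central 95% of 10000 random lists matched on level ran from -0.20 to 0.21. IFI27 differed by at least 5.50 and BST2, which tethers budding virus particles, by 3.36. Among antigen presentation genes 2 of 15 were at least 2-fold higher, PSMB9 of the immunoproteasome at 2.24 and TAPBP, a chaperone of peptide loading, at 1.49. Their median of 0.17 lay inside the random range. The NF-kB and inflammatory list was mixed, with 4 of 17 genes at least 2-fold higher and 2 lower, and its median of 0.21 also lay inside. The prostaglandin synthase PTGS2 differed by at least 3.22 and the siderophore-binding LCN2 by 5.37, while the chemokines CXCL3 and CCL20 differed by -1.06 and -1.02.

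Epithelial junction and keratin genes were higher as a group. Of 26 members 10 were at least 2-fold higher and 3 lower, with a median of 0.75 against a random range of -0.22 to 0.21. GRHL2, a transcription factor of epithelial cells, differed by at least 2.62 and the desmosomal cadherin DSC2 by 3.15. The tight junction gene CLDN1 went the other way, at -2.31, as did KRT7 at -1.58, although another probe set of KRT7 differed by 0.19. The mesenchymal list had a median of -0.29, below the random range of -0.22 to 0.21, with 3 of 13 genes at least 2-fold lower and none higher. VIM differed by -6.90 and SNAI2, a repressor of E-cadherin, by -2.25 or lower. The mesenchymal median lay inside the random range in 4 of 13 alternative settings, and was -0.084 with the probe set of smallest difference. Intestinal differentiation markers split, with 7 of 20 at least 2-fold higher and 2 lower and a median of 0.14 inside the range. KRT20, at 7.30 or more, and LGALS4, at 6.45 or more, stood against the goblet cell peptide TFF3 at -3.33 and the microvillus protein VIL1 at -1.25.

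Genes of drug efflux and detoxification were higher, 6 of 14 by at least 2-fold and 1 lower by as much. Their median of 0.72 stood above a random range of -0.26 to 0.24. ABCG2 differed by at least 4.69 and ALDH1A1 by at least 4.77. The efflux pumps ABCB1, at -0.27 or lower, and ABCC2, at -0.59, went the other way. The median of this list was 3.03 with the floor at the 75th percentile. The list of NRF2 and oxidative stress genes had a median of 0.48 against a range of -0.23 to 0.21. In it the aldo-keto reductase AKR1B10 differed by at least 3.36, the glutathione peroxidase GPX2 by 2.17 and the cystine transporter SLC7A11 by -0.72. Of 9 measured histone genes 5 were at least 2-fold higher and none lower, with a median of 1.07 against a random range of -0.34 to 0.37. H2AC6 differed by 2.01 and H2BC12 by 1.73. Without probe sets that can match several transcripts only 4 histone genes were left, with a median of 0.49 inside the random range.

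Genes of the ATF4 and amino acid response were lower on the SOX2 knockdown array. Of 25 members 23 lay below 0 and 16 were at least 2-fold lower, with none at least 2-fold higher. The median was -1.26 against a random range of -0.23 to 0.20. STC2, a secreted glycoprotein, differed by -4.48 or lower and DDIT4, an inhibitor of mTORC1 signalling, by -3.68. The arginine transporter SLC7A1 differed by 0.91 and the transcription factor CEBPB by 0.59; another probe set of SLC7A1 differed by -0.13. The unfolded protein response list had a median of 0.14 inside the random range, with 2 of 17 genes at least 2-fold higher and 2 lower. The chaperone genes DNAJB9 at 1.53 and PDIA6 at 1.29 stood against DDIT3 at -1.59 and HERPUD1 at -1.01. Heat shock genes had a median of -0.04, with BAG3 at 0.69 and CHORDC1 at -1.20. Of 24 hypoxia and glycolysis genes 6 were at least 2-fold lower, led by the glucose transporter SLC2A3 at -3.39 and by ANKRD37 at -2.18, but the median of -0.21 lay inside the random range. Cholesterol synthesis genes had a median of 0.05, with SQLE at 2.13 and NSDHL at 0.93 against HMGCS1 at -0.67 and ACAT2 at -0.65.

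Wnt and beta-catenin targets were lower as a group, 8 of 22 by at least 2-fold, while 3 were higher by as much. Their median was -0.73 against a random range of -0.23 to 0.24. BAMBI, a decoy receptor of TGF-beta signalling, differed by -5.11 or lower and NKD1, a feedback inhibitor of Wnt signalling, by -3.43, against the hyaluronan receptor CD44 at 3.86 and ETS2 at 2.64. The 9 probe sets of CD44 ranged from 0.13 to 3.86. With the probe set of smallest difference the Wnt median was -0.21, still below all but 0.98% of random lists. MAPK pathway feedback genes had a median of -0.51 against -0.31 to 0.31, with 7 of 18 at least 2-fold lower. EPHA4 differed by -1.69 or lower and ETV5 by -1.83, against EREG at 2.49 and SPRY1 at 0.75. The MAPK median was -0.057, inside the random range, when both arrays had to reach the floor. AP-1 and immediate early genes had a median of -0.40 against -0.22 to 0.22, with EGR3 at -1.14 or lower, ATF3 at -2.00, ZFP36 at 1.40 and CCN1 at 0.97. The AP-1 median lay inside the range in 4 of 13 alternative settings, and was -0.0076 without probe sets that can match several transcripts; another probe set of ATF3 differed by 0.11.

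Markers of intestinal stem cells and colorectal tumour-initiating cells went both ways. Of 14, 4 were at least 2-fold higher and 2 lower, and the median of 0.11 lay inside the random range. ALDH1A1, at 4.77 or more, and CD44 at 3.86 stood against ASCL2, a transcription factor of crypt base stem cells, at -2.98 and SMOC2 at -1.24 or lower. TGF-beta and BMP pathway genes had a median of 0.13 inside the range, with the ligand BMP2 at 1.66 or more and the receptor BMPR2 at 1.86 against BAMBI at -5.11 or lower and INHBB at -3.94. Notch pathway genes had a median of -0.05, with DTX4 at 3.12 or more and NRARP at 1.63 against HEY1 at -1.52 and JAG1 at -1.34. Growth factor genes of the FGF, EGF and IGF families had a median of 0.01, with 7 of 22 at least 2-fold higher and 3 lower. The receptor FGFR2 differed by at least 3.46 and the EGF receptor ligand EREG by 2.49, and FGFBP1 and IGFBP2 by -1.88 and -1.70. Other probe sets of BMPR2, FGFR2 and JAG1 differed by -0.19, -0.090 and 0.024.

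Genes of G2/M and mitosis were lower. Of 34 members 29 lay below 0, 7 were at least 2-fold lower and none higher, with a median of -0.45 against a random range of -0.23 to 0.20. The Aurora kinase AURKB differed by -1.71 and DLGAP5, a spindle protein, by -1.59. Genes of G1/S and DNA replication had a median of -0.01, with CCNE1 at 1.87 and CCNE2 at 1.33, both E cyclins, against the polymerase subunit POLA1 at -1.88 and the clamp loader RFC4 at -1.12. Among CDK inhibitors and D cyclins, whose median was -0.02, CDKN1A differed by 0.93, CDKN2B by -2.09 and CCND1 by -0.98. The p53 target list had a median of 0.10, with FAS at 1.64 and SESN1 at 0.95 against PMAIP1 at -2.24 and SESN2 at -1.68. The BCL2 family and apoptosis list had a median of 0.18, with CFLAR at 1.55 and BMF at 0.68 against BIK at -4.01 and PMAIP1. A further probe set of CFLAR differed by -0.0090. These 4 medians, from G1/S genes to apoptosis genes, lay inside their random ranges.

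Pluripotency factors other than SOX2 showed smaller differences. In the list with SOX2, TFCP2L1 differed by -1.64 or lower, 2 of 10 genes were at least 2-fold lower and the median was -0.16, inside the random range. Among 10 other SOX genes SOX8 differed by -1.23 or lower and SOX12 by -0.82, and the median was -0.08. Neural lineage genes had 3 of 7 at least 2-fold lower, among them SYT1 at -5.80 or lower and the progenitor filament NES at -3.66 or lower. The other probe set of NES differed by -0.043. The neural median of -0.37 lay inside a range of -0.42 to 0.40, and at the 1.52 percentile of random lists when values under the floor were raised to it. Matrix proteases and their inhibitors had a median of 0.06, with MMP7 at 6.09 and the cathepsin CTSD at 1.53 against the plasminogen activator PLAU at -3.14 and CTSB at -1.07. No cytosolic ribosomal protein gene of 23 and no oxidative phosphorylation gene of 25 differed by 2-fold at its brightest probe set, with medians of -0.02 and 0.01. Other probe sets of RPL37 and RPS23 differed by -1.42 and -1.40. The lowest oxidative phosphorylation genes were UQCRC1 at -0.91 and NDUFA9 at -0.63.

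Of 34 lists with at least 5 measured genes, 5 medians lay above their random range and 6 below it. By chance 1.7 in all would lie outside if genes varied independently, whereas differences here followed gene order along chromosomes. Some genes stood on more than 1 list, such as BAMBI and EREG. Of 104 genes named from the lists 49 had several probe sets, and in 21 of these at least 1 differed by under 1.5-fold or went the other way. Beside those given above they were VIL1 (-0.19), TAPBP (0.15), HERPUD1 (-0.16), SLC7A11 (-0.082) and AURKB (-0.34), and CDKN2B, HMGCS1, EREG, FBLN1, LAPTM5, SPRY1 and TFCP2L1. A percentile among random lists describes these 2 arrays only.

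**Figure D3:**
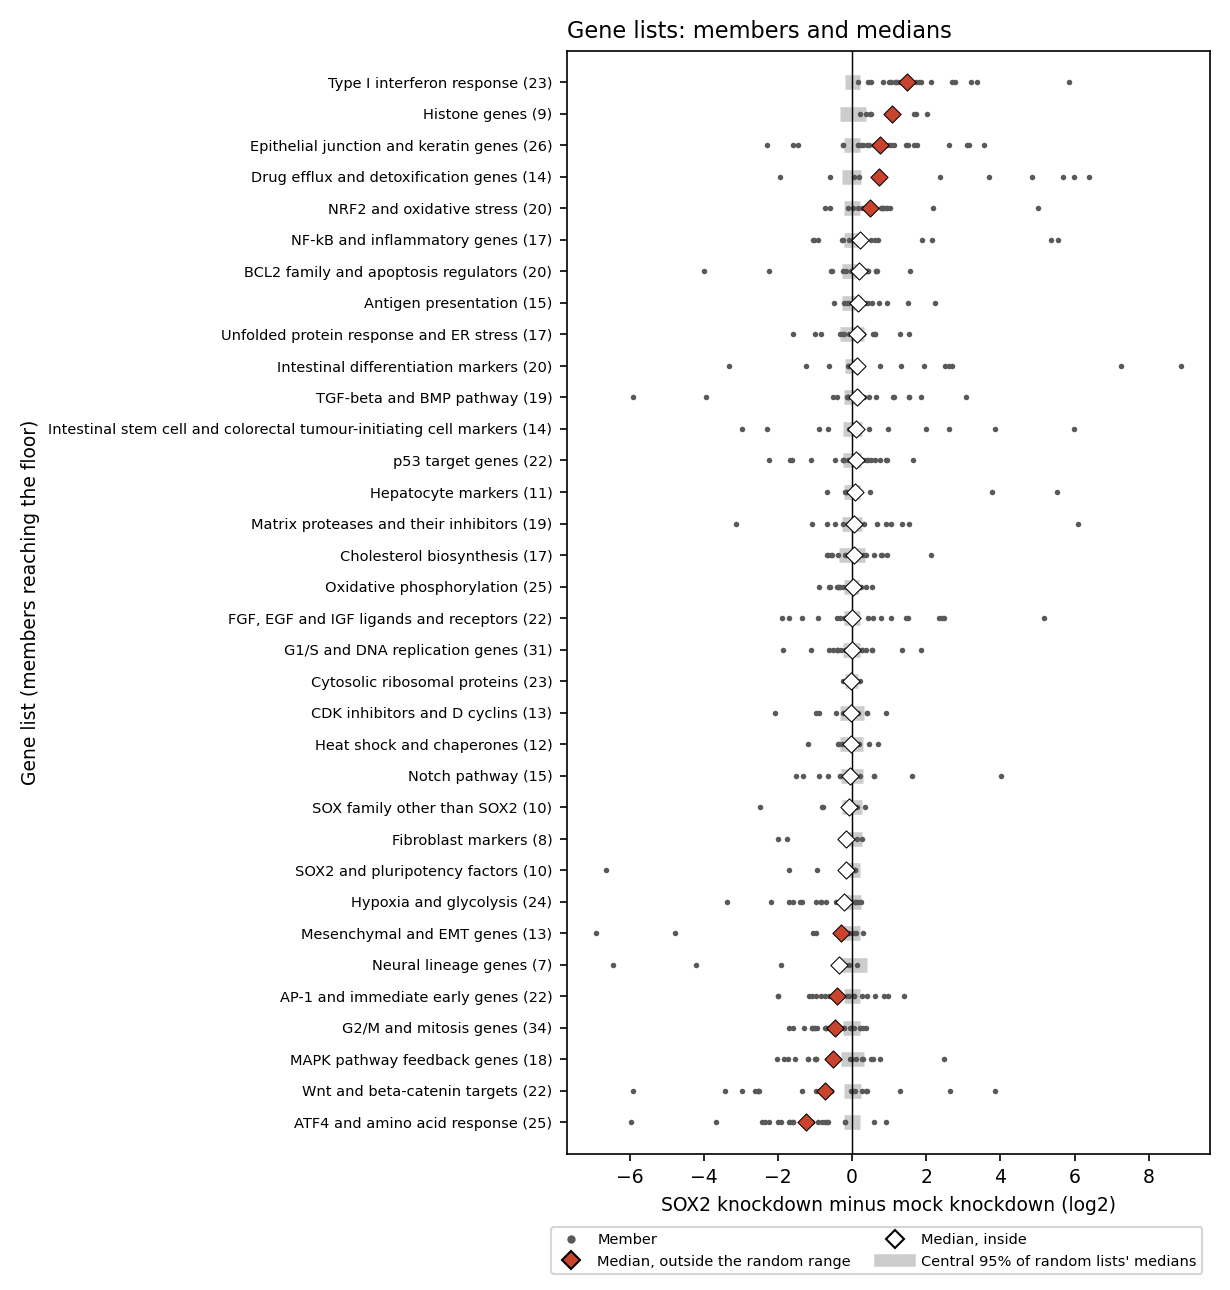
Log2 difference, SOX2 knockdown minus mock knockdown, of the members of each gene list reaching the floor (dots), with the list's median (diamond, filled where it lies outside the grey bar) and the central 95% of medians of 10000 random lists matched on level (grey bar). Values under the floor are plotted as deposited. The type I interferon list has the highest median, 1.47, and the ATF4 and amino acid list the lowest, -1.26.

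Markers of other cell types were looked at on each array because of a conflict in the labels. The description field of both samples names liver of mice with a changed ECM1 gene. The title, source, cell line, organism and protocol fields name SW620 with mock or SOX2 knockdown instead. ECM1 stood at 143 on the mock array and 149 on the SOX2 knockdown array, a difference of 0.06. Of 19 hepatocyte markers 9 reached the floor on the mock array and 11 on the SOX2 knockdown array, and none and 2 reached an intensity of 1000. The 2 were APOH, with a difference of at least 4.46, and SERPINA1, with 3.78, while ALB, the most abundant hepatocyte transcript, stayed under the floor at 4.43 and 4.32. The hepatocyte median of 0.08 lay inside the random range, and ASGR1 differed by -0.67. In contrast, 23 of 26 epithelial genes reached the floor on the mock array and all 26 on the other, with 12 and 16 at 1000 or more. Fibroblast markers had a median of -0.16 inside the range, with LUM at -0.07 or lower and FBLN1 at -1.75 and none at 1000. Leukocyte and endothelial markers had 4 measured genes each, too few for a comparison with random lists. Among them LYZ differed by 5.78, CD14 by at least 1.19, LAPTM5 by -1.57 and ESAM by 1.73. Of 13 leukocyte markers 3 reached the floor on the mock array and 4 on the SOX2 knockdown array. PTPRC (4.06 and 4.31), CD3D (5.92 and 5.79) and CD3E (5.95 and 5.94) reached it on neither.

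Hybridization control probe sets differed little between the arrays, and other kinds of control differed more. The 18 hybridization spike-in probe sets differed by at most 1.07-fold. Of 27 labelling spike-in probe sets, the 24 that reached the floor were brighter on the SOX2 knockdown array, by up to 1.26-fold. The other 3, all for trpn, lay under the floor on both arrays, with differences from -0.22 to 0.03. The 5′ control probe sets of ACTB and GAPDH differed by -0.37 and -0.23. Those named HUMRGE differed by 0.26 to 0.31. The ratio of 3′ to 5′ signal, which rises as RNA degrades, was 1.20 for ACTB on the mock array and 1.43 on the SOX2 knockdown array, and 1.04 and 1.06 for GAPDH.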

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

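The count in this part was chosen only after the data were examined. Probe sets that the annotation gives no gene symbol, or several, entered none of the gene comparisons. Of 4422 such probe sets that reached the floor, 195 were at least 2-fold higher on the SOX2 knockdown array and 227 at least 2-fold lower, together 9.54%. This was a lower share than the 15.7% of the 13609 genes, each counted at its brightest probe set. No explanation was tested for them.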

How the results depend on the processing

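All alternatives in this part were fixed beforehand, except that raising values under the floor to the floor was chosen only after the result was seen. None could leave out a replicate, since each group held 1 array. No paired analysis was possible because each group held 1 array and no test was run. The gene counts stayed within 1.5 times of the reported ones in 24 of 30 alternatives. The exceptions follow from their limits: at 1.5-fold, 2044 genes were higher and 2012 lower; at 3-fold, 604 and 467; at 2-fold and beyond 3 local spreads, 664 and 543. The SOX2 difference of -6.64 was -4.05 as the mean of its probe sets, -1.47 with the probe set of smallest difference, -5.32 with a pseudocount of 32 and -4.92 with values raised to the floor. It had no value where both arrays had to reach the floor. Of 1298 alternative values of named genes 618 were identical to the reported ones, many because the setting cannot move a gene with 1 probe set. Of the others 507 moved by less than the spread between probe sets, 165 by more, and 8 changed sign. With the probe set of smallest difference the sign changed for ATF3 (0.11), BMPR2 (-0.19), CFLAR (-0.0090), FGFR2 (-0.090), JAG1 (0.024), SLC7A1 (-0.13) and KRT7 (0.19), and KRT7 was also at 0.19 without probe sets that can match several transcripts. No list median outside its random range changed sign, and of 143 alternative values 29 were identical, 75 moved by less than the SD of random medians and 39 by more. The 3 normalizations moved none by more. Random lists not matched on level cannot move a median; with them mesenchymal genes fell inside the range and hypoxia genes below it.

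The other medians were as follows, and beyond what each setting's own construction shows the cause was not tested. Without a floor, Wnt targets were at -0.56, mesenchymal genes at -0.11, interferon genes at 1.28 and histone genes at 0.79. With the floor at the 75th percentile, Wnt targets were at -0.88, mesenchymal genes at -0.97 and drug efflux genes at 3.03. With both arrays reaching the floor, Wnt targets were at -0.56, epithelial genes at 0.59, interferon genes at 1.31, MAPK feedback genes at -0.057 and histone genes at 0.79. Without probe sets that can match several transcripts, Wnt targets were at -0.88, epithelial genes at 0.91, G2/M genes at -0.58, AP-1 genes at -0.0076, MAPK feedback genes at -0.97, ATF4 genes at -1.12, NRF2 genes at 0.36 and histone genes at 0.49. With the probe set of smallest difference, Wnt targets were at -0.21, epithelial genes at 0.51, mesenchymal genes at -0.084, interferon genes at 1.17, AP-1 genes at -0.076, MAPK feedback genes at -0.14 and NRF2 genes at 0.37. The mean of the probe sets gave interferon genes 1.36 and AP-1 genes -0.19, and the pseudocount gave interferon genes 1.21 and histone genes 0.88. With values raised to the floor, epithelial genes were at 0.63 and interferon genes at 1.31. As means in place of medians, Wnt targets were at -0.86, mesenchymal genes at -1.11, interferon genes at 1.75, ATF4 genes at -1.44, NRF2 genes at 0.72 and drug efflux genes at 2.10. The median fell inside its random range in 4 of 13 settings for mesenchymal genes, 4 for AP-1 genes, 2 for MAPK feedback genes, 1 for histone genes and 0 for the other 7 lists outside it. Signal over background limits the differences of genes under the floor on 1 array, for which only a bound holds.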

Other observations

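Of the tests in this part, the correlation between genes 20 to 60 apart was set down before its result was seen, and all the others were chosen only after the large differences were seen. So were the genes of this paragraph, which stand for no group beyond themselves and are given as values. PLA2G4A, the phospholipase that releases arachidonic acid, differed by at least 3.09, and HPGD and PTGR1, which break prostaglandins down, by at least 4.36 and 4.17. The tetraspanin TSPAN8 differed by 5.61 and the trafficking GTPase RAB25 by at least 5.21. LCK, a kinase of T cell receptor signalling, stood at 11.03 on the mock array and under the floor on the other, a difference of -4.93 or lower. LCP1, the leukocyte plastin, differed by -4.94 or lower. The T cell markers CD3D, CD3E and CD2 and the leukocyte marker PTPRC lay under the floor on both arrays. All 9 measured genes with BEX or TCEAL symbols lay below 0, 6 of them by at least 2-fold, against 992 of all 13609 genes. Among them were BEX3 at -6.26 or lower, TCEAL4 at -2.66 and TCEAL8 at -2.16. This count was not tested. Genes 1 to 5 apart on a chromosome tended to differ alike, with a correlation of 0.178. Where these 9 genes lie was not examined, so they cannot be taken as independent.

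Genes bright on 1 array and dim on the other were found in both directions, 55 at least 16-fold higher and 38 at least 16-fold lower on the SOX2 knockdown array, against the floor. A mixture, in which the array labelled SOX2 knockdown held 10% or more of unchanged mock-like cells, would leave genes at least 10% of their mock level. Values under the floor were taken at the floor. Of 2724 genes with an intensity of 1000 or more on the mock array, 55 kept under 10% of it. Of the 881 bright enough to show it, 7 kept under 2.5%. For these genes, at their brightest probe sets, the values argue against such a share. The limits were set after the large differences were seen, so the count is no independent test. Among the 7, other probe sets of ELOVL5 and CLDN11 differed by only -0.42 and -0.63. Among 12383 genes reaching the floor on both arrays, differences limited to 1 either way correlated at 0.105 between genes 20 to 60 apart on a chromosome, before and after regression on mean level and gene length (at most 0.0041 and 0.0053 in 1000 shuffles), at 0.0755 when not limited and at 0.0668 by sign alone, with 0.0954 to 0.114 without any 1 chromosome. The correlation was 0.178 between genes 1 to 5 apart and 0.0544 at 61 to 150 genes. Median differences of 15 of 23 chromosomes lay outside the 95% range of shuffles, where 1.15 would by chance and at most 6 did in any shuffle. They ran from -0.228 to 0.230, against -0.141 to 0.130 over all shuffles. These values go with cells of different karyotypes, such as different lines or clones, as a hypothesis. Shared regulation over long chromosome domains was not tested and stays open. The regression covered only mean level and gene length, so technical causes that follow gene order were not tested either. Loss of SOX2 itself, the explanation the design names, cannot be told apart from any other difference between the cultures, because each group held 1 array.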
